A study of Mus musculus with 6 samples.

How the data were processed

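Posterior tissue of mouse embryos at E9.5, in 3 Fkbp8 mutant and 3 wildtype samples, was profiled on 1-colour CodeLink Mouse Whole Genome arrays. Per the labels' protocols, the tissue was dissolved in trizol, total RNA was purified on columns, and targets were made with the CodeLink expression assay. The groups and the replicate letters a to f were taken from the sample titles. Nothing in the labels pairs mutant with wildtype samples. In the file headers the sample names of mutant a and wildtype d begin with the same number, whose meaning is not stated there. The deviations of these samples from their group means correlated across probes at 0.127, against -0.137 to 0.077 for the other mutant and wildtype pairs, and probes are not independent replicates. With a single such pair no block was fitted. The source label of mutant a reads embryos in the plural, so pooling is not settled for that sample, and the p-values measure the spread between these 6 samples.

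Each scanner table held 36227 spots, of which 34967 were probes for genes and the rest fiducial (640), negative control (320) and positive control (300) spots. Spots were quantified with the CodeLink Expression Analysis software, per the file headers, as intensity (mean of the spot and median of its local background). The deposited background-subtracted intensity equalled spot mean minus background median, within 0.0001, at unmasked spots. The deposited normalized intensity was that difference divided by 1 factor per array, close to the median of the gene probes, and the values of the deposited series table equalled it exactly (largest difference 0, median 1 on each array). The scale of that table is therefore linear, and each array was centred on its own median. Background medians were 47 to 53 and median background-subtracted intensities 52.1 to 65.1, lowest in mutant c. Between 21 and 33 gene probes per array were saturated and were kept.

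Probe names came from the platform annotation where its accession and that in the array file were the same (21781 of 21880 listed probes). Symbols were updated through Entrez IDs with the RefSeq gene table of GRCm38.p6 (21442 probes) or kept as given (135), and 417 further probes were named through a RefSeq accession and 542 by the symbol in the array file. In all, 22536 probes had 1 symbol, 204 several and 12227 none. No coordinates of that assembly are given, since the build behind the array design is not given in the sources used here. It served for names and for gene order only.

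The following choices were made before the data were examined, unless said otherwise. Background was corrected with normexp (offset 50) on spot mean and background median over all spots of an array. Control spots were then left out, spots marked contaminated, irregular or masked (339 to 508 per array) were set to missing, and log2 values were quantile-normalized between arrays. Probes marked good or saturated by the scanner software, here called above background, on at least 3 of 6 arrays and with at least 2 usable spots per group were tested. Mutant and wildtype were compared per probe with limma (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all 21688 probes tested (15390 with 1 symbol, for 13359 genes) and a threshold of 0.05. The normexp offset makes the fold changes of dim genes smaller than they are. Where a probe was not above background on any array of a group, the fold is given as a bound. It sets the mean log2 value of the brighter group against the mean of, per array, the higher of the probe's own value and the lowest value among probes above background. Errors of log2 fold changes are standard errors from limma. Single values were also compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3.

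Gene lists were tested with camera from limma (preset correlation 0.01) on 1 probe per gene, the brightest over all arrays, with adjustment over the 41 lists. They covered neural tube patterning and signalling responses, cell types of the posterior embryo, other cell types that a dissection could hold, sex-linked genes, cell death and stress, and cell cycle. A list needed at least 4 tested members. An estimated correlation and fry were alternatives. Genes named in the text follow a rule. They are Fkbp8, up to 12 named genes per direction with the largest change past the threshold and above background on all arrays of the higher group (filled by the smallest p where fewer passed, and then given as not passed), up to 4 members with the smallest p of each list described, and 9 patterning genes fixed by name where measured.

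The alternatives were median centring and cyclic loess in place of quantile normalization, background-subtracted values with a floor of 1, no background correction, the deposited series table and the scanner's normalized intensity, no filter or a filter on all 6 arrays, an intensity trend, array weights, a 2-fold minimum, an adjusted p under 0.1, the mean of all probes of a gene for lists, and leaving out each array in turn. Leaving out genes of chromosomes X and Y, keeping contaminated and irregular spots, and the erythroid mean as a covariate were added after seeing the data. A slide block was not run. Each slide held 1 array, and in the file headers the slide numbers of the mutants all precede those of the wildtypes, so that slide order and genotype cannot be told apart.

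The gene and list tests were tested on simulated data with the means and spread of the 21688 probes and 3 arrays per group, in 10 simulations. Of 100 probes changed by 2-fold, 96 on average passed, and of 100 changed by 0.5 on the log2 scale, 34.3 passed, with 5.5 unchanged probes called per simulation. A list shifted by 0.25 was called in 10 of 10 simulations, and on average 0.3 unshifted lists were called per simulation. The changes were added to the normalized log2 values, after the normexp offset. The rates therefore do not cover the shrinking of fold changes at dim probes, where fewer true 2-fold changes would pass. The simulated probes were drawn independently of each other, so these rates do not cover correlation between the genes of a list. R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.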

Results

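Gene expression was measured in the posterior part of mouse embryos at E9.5, in the tissue just behind the forelimb bud. Tissue in 3 samples of Fkbp8 mutants (replicates a, b and c) was compared with tissue in 3 samples of wildtypes (replicates d, e and f). Whether mutant a was 1 embryo or a pool is not settled. The embryos came from crosses between heterozygous carriers, and each sample was hybridized to its own 1-colour array. Fkbp8 encodes an FK506-binding protein family member that anchors in the outer mitochondrial membrane and binds BCL2. The series asks, by its title, how the gene acts on cell death and on dorsoventral patterning of the posterior neural tube. Each array carried 34967 probes for genes, of which between 20144 (57.6%, mutant c) and 21612 (61.8%, wildtype f) were above background. Between arrays of 1 group, log2 intensities correlated across probes at 0.992 to 0.993 in wildtype and at 0.984 to 0.988 in mutants. Mutant and wildtype arrays correlated at 0.984 to 0.989. The median standard deviation of a probe over 3 arrays was 0.09 in wildtype and 0.11 in mutants on the log2 scale. The small number of arrays limits the precision of every value below.

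Fkbp8 signal was lost in the mutants. The log2 intensity of Fkbp8 averaged 10.66 ± 0.09 (SD, n = 3) in wildtype and 6.23 ± 0.10 (SD, n = 3) in mutants, where its probe was above background on 0 of 3 arrays. The gene was therefore at least 18.8-fold lower in mutants, with a fitted log2 fold change of -4.43 (SE 0.09, limma adjusted p = 1.18e-07). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 against 3 allows. The labels do not describe the mutation, and where the probe lies relative to it is not stated in the sources used here.

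Besides Fkbp8, the named genes that differed included dorsoventral patterning genes of the neural tube, Ccdc124 and genes of the sex chromosomes. Of 21688 probes tested, 26 passed an adjusted p of 0.05 in limma, 14 higher and 12 lower in mutants, and the groups did not overlap for any of the 26. Of these, 20 carried 1 gene symbol (11 higher, 9 lower), and 12 of the 26 had a fitted change of at least 2-fold. The Y-linked Uty is among the 12, although its bound was only 1.81-fold. At an unadjusted p under 0.05 there were 2654 probes (12.2% of those tested). The groups did not overlap for 4283 probes (19.8%), where chance gives 10%.

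Among the named autosomal genes past the threshold over all probes, the transcription factors Nkx6-1 and Foxa2, both of the ventral neural tube, rose most. Nkx6-1 rose 2.21-fold, from 9.78 ± 0.17 to 10.92 ± 0.14 (log2 intensity, SD, n = 3 each, adjusted p = 0.00853). Foxa2, made in the floor plate and notochord, rose 2.12-fold, from 8.05 ± 0.06 to 9.14 ± 0.31 (adjusted p = 0.0403). Smaller rises passed the test for Fhdc1 (log2 fold change 0.81, SE 0.08), for the metalloproteinase inhibitor Timp4 (0.75, SE 0.09) and for Arl4a (0.55, SE 0.07). Nhlh2, a transcription factor of young neurons, was above background on 0 of 3 wildtype and 3 of 3 mutant arrays and rose at least 1.52-fold (adjusted p = 0.0456). Its spot number (2259) is next to that of the brighter Fhdc1 (2260), and the local background there was not examined. Adat2 was 0.59 higher (SE 0.09) and did not pass (adjusted p = 0.0701).

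Among the neural patterning genes past the threshold over all probes, Pax6 fell most, with a log2 fold change of -1.15 (SE 0.09, adjusted p = 0.00287), from 8.88 ± 0.15 to 7.73 ± 0.07 (SD, n = 3 each). Irx3 (-0.65, SE 0.07, adjusted p = 0.0178) and Prdm13 (-0.94, SE 0.13, adjusted p = 0.0468), further transcription factors of the neural tube, fell as well, and Prdm13 was above background on 1 of 3 mutant arrays. Scube2, a secreted protein that helps release hedgehog ligands, fell with a log2 fold change of -0.97 (SE 0.10, adjusted p = 0.0118). Ccdc124 fell 2.48-fold, from 10.49 ± 0.08 to 9.18 ± 0.07 (SD, n = 3 each, adjusted p = 0.000395). In the gene order of the GRCm38.p6 assembly, Ccdc124 lies on the chromosome of Fkbp8 with 14 other tested genes between them. Bst2 was above background on 0 of 3 mutant arrays and fell at least 1.46-fold (adjusted p = 0.037). Its position relative to Fkbp8 was not examined. Csnk2a1, a catalytic subunit of casein kinase 2, had a log2 fold change of -0.54 (SE 0.07, adjusted p = 0.0431). Zic1 (-1.0, SE 0.14, adjusted p = 0.0505), the X-linked Hccs (-0.51, SE 0.07, adjusted p = 0.0534) and Crk (-0.80, SE 0.12, adjusted p = 0.0951) did not pass. Over the alternatives, Zic1 passed in 5 of 19 settings (lowest adjusted p = 0.0259, without wildtype d). Hccs passed in 2 of 18 (lowest 0.0464) and Crk in 1 of 19 (0.0493).

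**Figure D1:**
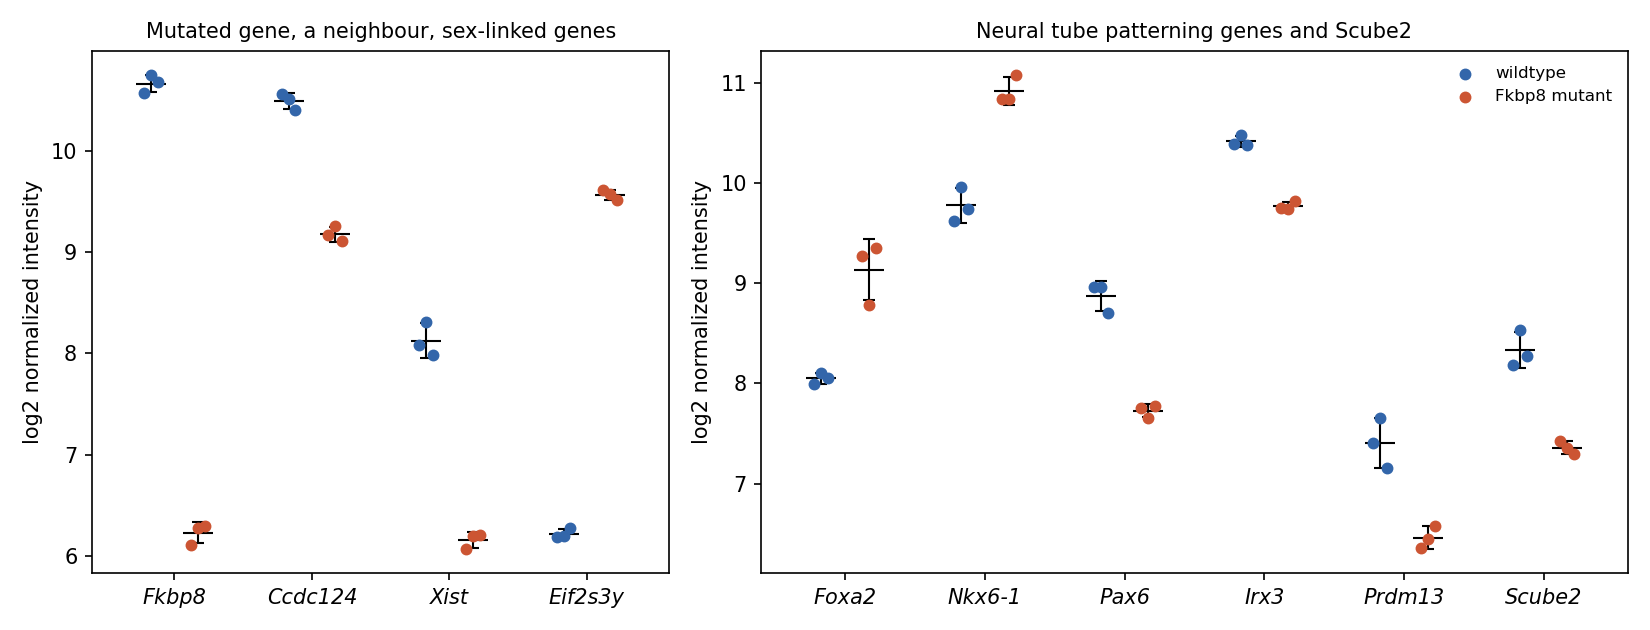
Log2 normalized intensity (y axis) of 10 genes (x axis) on each array, with wildtype in blue and Fkbp8 mutant in red; points are arrays, horizontal bars are means and whiskers are the SD (n = 3). Fkbp8 averaged 10.66 in wildtype and 6.23 in mutants, Nkx6-1 and Foxa2 were higher on every mutant array, and Pax6, Irx3, Prdm13, Scube2 and Ccdc124 were lower on every mutant array.

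The Y-linked genes Eif2s3y, Ddx3y and Uty were above background on 3 of 3 mutant arrays and on 0 of 3 wildtype arrays. Xist, the RNA made from the inactive X chromosome of females, showed the reverse, with 3 of 3 wildtype and 0 of 3 mutant arrays. Eif2s3y was at least 8.97-fold, Ddx3y at least 2.49-fold and Uty at least 1.81-fold higher in mutants, and Xist was at least 3.25-fold lower (adjusted p = 1.61e-07, 0.00646, 0.000709 and 0.000107). Kdm5d, also Y-linked, rose by 0.63 on the log2 scale (SE 0.08, adjusted p = 0.0403) but was above background in wildtype too. The X-linked Xlr3b rose 2.22-fold (adjusted p = 0.00287). The sex-linked list passed camera (adjusted p = 2.42e-05; adjusted p = 0.158 with an estimated correlation). Genotype and sex-linked expression were thus not separable in these arrays, for these genes and for every other gene described. Without the genes of chromosomes X and Y, an alternative added after seeing the data, 14 probes passed instead of 26. The removal took out the 6 called genes of these chromosomes. Probes without a single symbol had no assigned chromosome and stayed in, so the 14 may include sex-linked probes. Foxa2 (adjusted p = 0.0564), Nhlh2 (0.0607), Prdm13 (0.0607), Arl4a (0.0607) and Csnk2a1 (0.0579) no longer passed. The log2 fold changes of these 5 autosomal genes stayed as they were, and only the adjustment and the variance shared across probes changed, so these losses say nothing about sex.

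Of the 26 probes, 6 had no single gene symbol. The probes GE1556434, GE1520500 and GE37917 were above background on 3 of 3 mutant and 0 of 3 wildtype arrays. They were at least 3.11-fold, at least 1.38-fold and at least 1.43-fold higher in mutants (limma adjusted p = 9.87e-06, 0.0125 and 0.0178). GE1425752 (log2 fold change -1.03, SE 0.11, above background on 1 of 3 mutant arrays), GE110529 (-0.82, SE 0.10) and GE127025 (-0.63, SE 0.09) were lower.

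Several calls rested on all 6 arrays being used. The count of 26 was 11 without mutant b, 11 without wildtype d, 14 without wildtype e and 11 without wildtype f. Pax6, Ccdc124, Xlr3b, Eif2s3y, Uty and Xist passed in every setting in which they were tested. Nkx6-1 had an adjusted p of 0.0588 without wildtype d and 0.0594 without wildtype f, and Scube2 of 0.0638 without mutant b and 0.0637 without wildtype f. Foxa2 had 0.112 without mutant b, 0.108 without mutant c, and 0.237, 0.165 and 0.209 without wildtype d, e and f. The corresponding adjusted p of Irx3 was 0.0632, 0.0689, 0.109, 0.114 and 0.092, and that of Prdm13 was 0.0901, 0.109, 0.128, 0.247 and 0.118 without a, b, c, d and e. Ddx3y lost its call without wildtype d (0.0588) or f (0.0558), and Fhdc1 without mutant b (0.0544), wildtype d (0.0828) or e (0.0788). Nhlh2 (adjusted p 0.1 to 0.233) and Kdm5d (0.0908 to 0.209) lost theirs without any array but mutant a. Timp4 (0.0516 to 0.118), Arl4a (0.0971 to 0.233), Csnk2a1 (0.0761 to 0.228) and Bst2 (0.0806 to 0.2) lost theirs whichever array was left out. With the deposited values the adjusted p was 0.0684 for Nkx6-1, 0.118 for Foxa2, 0.16 for Irx3 and 0.118 for Prdm13. With the erythroid mean as a covariate, added after seeing the data, it was 0.194, 0.407, 0.257 and 0.147 for these genes and 0.257 for Scube2. Their log2 fold changes with the covariate were 1.14 (SE 0.16, against 1.14, SE 0.11, without it), 1.15 (SE 0.20, against 1.08, SE 0.14), -0.67 (SE 0.10, against -0.65, SE 0.07), -1.14 (SE 0.15, against -0.94, SE 0.13) and -0.96 (SE 0.14, against -0.97, SE 0.10). These calls ended with a larger SE (median ratio 1.38 over all probes) and 3 instead of 4 residual degrees of freedom, as the covariate correlated with genotype (0.664).

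Among 41 gene lists fixed beforehand, 10 passed camera with a preset correlation, 5 shifted up and 5 shifted down in mutants. With an estimated correlation in camera 0 lists passed (smallest adjusted p = 0.144, with 5 at an unadjusted p under 0.05), and 5 passed fry, which tests against no change, 3 of them among the 10. Besides the sex-linked list, the smallest camera p belonged to lists of the neural tube that shifted in opposite directions, with ventral genes higher and intermediate genes lower. The list of floor plate and ventral progenitor genes had 6 tested members, 5 of them higher in mutants, and a mean log2 fold change of 0.73 (camera adjusted p = 6.12e-05; adjusted p = 0.175 with an estimated correlation; fry adjusted p = 0.0117). Without the filter on dim probes, which left out 6 further members, the mean over 12 members was 0.35 (camera adjusted p = 0.0117). Over all genes tested, 2 members rose, Nkx6-1 and Foxa2, and 4 rose when adjusted over the list alone, with Spon1 (0.67, SE 0.13) and Nkx2-9 (1.44, SE 0.29) added. Olig2, a gene of motor neuron progenitors, had a log2 fold change of -0.16 (SE 0.13, adjusted p = 0.659). Nkx2-2 was too close to background to be tested. The probes of Shh, the ligand made by notochord and floor plate, disagreed in sign, at 0.21 (SE 0.12) and -0.30 (SE 0.18), and neither passed (adjusted p = 0.503 and 0.534).

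All 9 tested genes of intermediate neural progenitors had negative log2 fold changes, with a mean of -0.57 (camera adjusted p = 2.24e-08; adjusted p = 0.144 with an estimated correlation; fry adjusted p = 0.00438). Over all genes tested, 3 members fell (Pax6, Irx3 and Prdm13), and 6 fell when adjusted over the list alone. The added members were Dbx1 (-1.26, SE 0.25), Irx5 (-0.38, SE 0.10) and Gsx1 (-0.33, SE 0.12). The call of this list and that of the ventral list held without each array in turn.

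Hedgehog response genes were higher on balance, with 8 of 11 members positive and a mean of 0.25 (camera adjusted p = 0.0204; adjusted p = 0.346 with an estimated correlation). The median of the list was lower, at 0.19. Over all genes tested 0 members passed in limma, 6 had an unadjusted p under 0.05, and 3 rose when adjusted over the list alone. These were the receptor Ptch1 (0.48, SE 0.08), Nkx2-9 (1.44, SE 0.29), which is also in the ventral list, and the transcription factor Gli1 (0.23, SE 0.07). The dimmer probe of Ptch1 had a log2 fold change of 0.10 (SE 0.11). The list did not pass without mutant b (adjusted p = 0.0894) or wildtype d (0.0698), nor with fry (0.064). The list of hedgehog pathway components did not pass (camera adjusted p = 0.904).

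Roof plate and dorsal progenitor genes were lower on balance, with 9 of 14 members negative and a mean of -0.16 (camera adjusted p = 0.0287; adjusted p = 0.346 with an estimated correlation). Over all genes tested 0 members passed in limma (7 at an unadjusted p under 0.05), and Zic1, Wnt3a (-0.47, SE 0.08) and Olig3 (-0.40, SE 0.09) made up the 3 that fell when adjusted over the list alone. Pax3, a marker of the dorsal neural tube, had log2 fold changes of -0.15 (SE 0.07) and -0.08 (SE 0.08) at its probes and did not pass. The list did not pass without mutant a (adjusted p = 0.0658), mutant b (0.0704) or wildtype e (0.0625), nor with deposited values (0.0577) or fry (0.0526). With median centring its camera adjusted p rounded to the threshold itself (0.05).

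**Figure D2:**
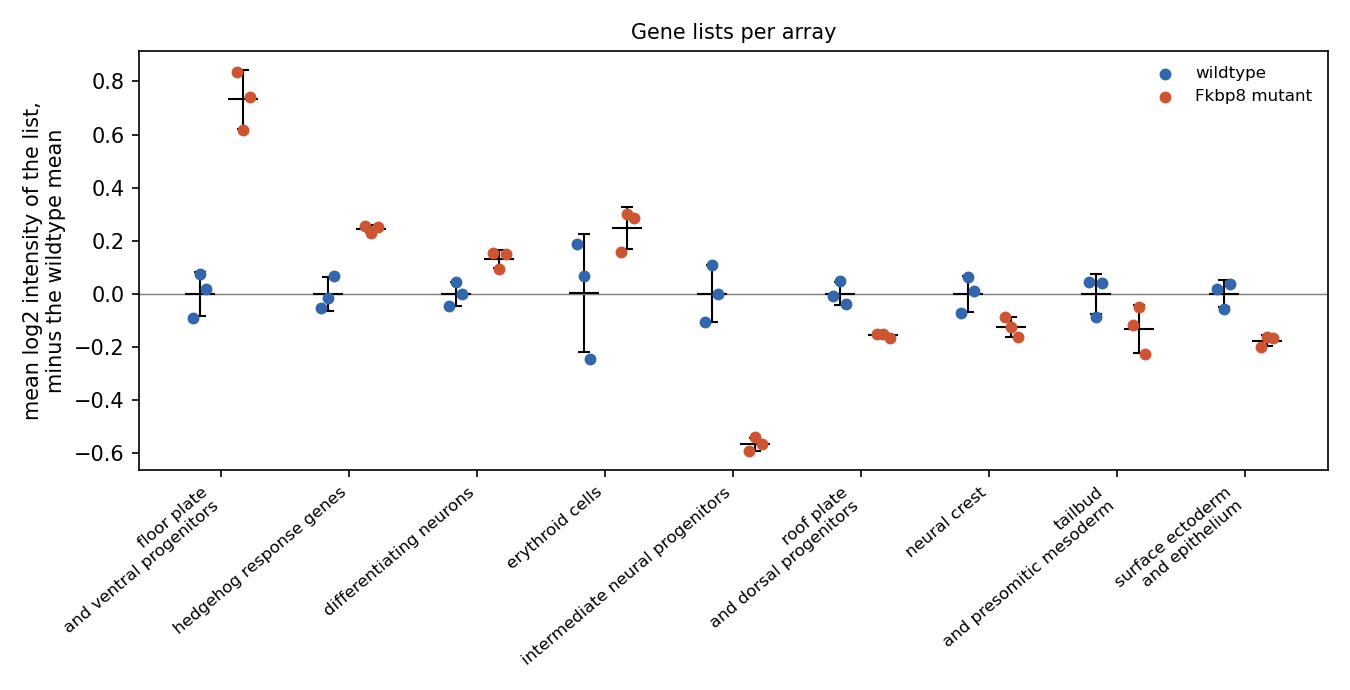
Mean log2 intensity of 9 gene lists (x axis) on each array, minus the wildtype mean (y axis, log2), with wildtype in blue and Fkbp8 mutant in red; points are arrays, horizontal bars are means and whiskers are the SD (n = 3). The ventral list lay between 0.62 and 0.84 on the mutant arrays and the intermediate list between -0.59 and -0.54, while the erythroid list overlapped between the groups.

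Genes of differentiating neurons were higher on balance (15 of 23 members positive, mean 0.13, median 0.03, camera adjusted p = 0.0491; adjusted p = 0.505 with an estimated correlation). Over all genes tested Nhlh2 rose, and 2 members rose when adjusted over the list alone, with the proneural factor Neurod4 (0.80, SE 0.12, adjusted p = 0.082 over all genes) added. The list passed in 8 of 22 settings, and did not pass without mutant b (0.0894), mutant c (0.121) or wildtype d (0.131). It also did not pass with median centring (0.15), floored values (0.0665), no background correction (0.0735), deposited values (0.129), the filter on all 6 arrays (0.0672), array weights (0.0541), fry (0.0677), X and Y genes left out (0.0516) or contaminated and irregular spots kept (0.0508). The pan-neural progenitor list did not pass (camera adjusted p = 0.409), and Hes3 (-0.73, SE 0.12) was its 1 member that fell when adjusted over the list alone.

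Neural crest genes were lower on balance (11 of 16 members negative, mean -0.13, camera adjusted p = 0.0204; adjusted p = 0.517 with an estimated correlation). Over all genes tested 0 members passed in limma (5 at an unadjusted p under 0.05), and 2 fell when adjusted over the list alone, Sox10 (-0.55, SE 0.12) and the receptor Erbb3 (-0.32, SE 0.08). Genes of the tailbud and presomitic mesoderm had 14 of 22 members negative and a mean of -0.13 (camera adjusted p = 0.0287; adjusted p = 0.517 with an estimated correlation). Wnt3a, also in the dorsal list, and Cdx1 (-0.48, SE 0.12) were the 2 members that fell when adjusted over the list alone, and 0 passed over all genes tested in limma (4 at an unadjusted p under 0.05). Genes of surface ectoderm and epithelium had 14 of 17 members negative and a mean of -0.18 (camera adjusted p = 0.0288; adjusted p = 0.505 with an estimated correlation). In limma 0 of them passed over all genes tested or when adjusted over the list alone (3 at an unadjusted p under 0.05), and Tfap2c (-0.78, SE 0.22), above background on 1 of 3 mutant arrays, had the smallest p. With fry 0 of these 3 lists passed (0.182, 0.282 and 0.182 in the order given), and the ectoderm list did not pass with the filter on all 6 arrays (0.253, mean -0.06). The neural crest list did not pass without mutant b (0.0746) or wildtype e (0.0625). The tailbud list did not pass without mutant b (0.133, mean -0.08), mutant c (0.0635), wildtype d (0.131) or f (0.0533), nor the ectoderm list without mutant a (0.29), b (0.133), wildtype d (0.0698) or f (0.0628).

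Markers of erythroid cells, which circulate in the embryo at this stage, were higher in mutants on balance, but their list means overlapped between the groups (18 of 19 members positive, mean 0.25, camera adjusted p = 0.00024; adjusted p = 0.517 with an estimated correlation; fry adjusted p = 0.276). In limma, 0 members passed over all genes tested or adjusted over the list alone (6 at an unadjusted p under 0.05), and Alas2 (0.41, SE 0.12) and Rhag (0.22, SE 0.07) had the smallest p. Relative to the wildtype mean, the list stood at 0.30, 0.29 and 0.16 in mutants a, b and c and at 0.19, 0.07 and -0.25 in wildtype d, e and f. Without wildtype f the list did not pass (camera adjusted p = 0.0533), and its mean log2 fold change was 0.12 instead of 0.25. With this list's mean as a covariate, an alternative added after seeing the data, 9 probes and 6 lists passed, and the neural crest, tailbud and ectoderm lists were not among the 6 (adjusted p = 0.168, 0.0883 and 0.22). Their means kept their sign, at -0.09, -0.11 and -0.17. The macrophage (camera adjusted p = 0.303), endothelium (0.793) and heart muscle (0.506) lists did not pass.

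For cell death, the other process in the series title, no list passed camera. Among 24 tested p53 target genes, 13 were higher and 11 lower (camera adjusted p = 0.948), and 8 had an unadjusted p under 0.05. Over all probes tested that share was 12.2%, and whether a cell death list exceeds it was not tested. Camera looks for a shift in a single direction, so it does not address changes that go both ways. For change in either direction, fry gave a mixed p under 0.05, not adjusted over lists, for 26 of the 41 lists. The p53 list (0.000682) and that of the BCL2 family and caspases (2.89e-05) were among them. That test does not compare a list with other genes. Pmaip1, a proapoptotic BH3-only gene, was lower (-0.55, SE 0.09, adjusted p = 0.106 over all genes) and was the 1 member that fell when adjusted over the list alone. Bbc3 (0.25, SE 0.07) and the cell cycle inhibitor Cdkn1a (0.32, SE 0.10) did not pass. Among 25 genes of the BCL2 family and caspases, 17 were higher (camera adjusted p = 0.346), with Bik (0.30, SE 0.08), Bak1 (0.42, SE 0.12) and Bnip3 (0.31, SE 0.09) at the smallest p, and 0 members past the threshold in limma (7 at an unadjusted p under 0.05). The list of the integrated stress response and unfolded protein response did not pass camera (adjusted p = 0.445) but passed fry (adjusted p = 0.0216). Vldlr was its 1 member that rose when adjusted over the list alone (0.66, SE 0.12, above background on 2 of 3 mutant arrays), while Ddit3 (0.39, SE 0.12) and Hspa5 (-0.29, SE 0.10) did not pass. Heat shock chaperones (0.508), hypoxia and glycolysis (0.256), mitophagy and autophagy (0.948), the FK506-binding protein family (0.701) and the mTOR pathway (0.545) did not pass camera at the adjusted p given.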

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

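The removal of X and Y genes, the keeping of contaminated and irregular spots and the erythroid covariate were alternatives chosen after seeing the data, and the others were planned. The 26 probes past the threshold became 16 with median centring, 13 with background-subtracted values floored at 1, 15 with the deposited series table, 15 with the scanner's normalized intensity (the same values), 16 when every array had to be above background, 12 with a 2-fold minimum, 14 without X and Y genes and 9 with the erythroid covariate. Leaving out each array gave 11 to 37 probes. All 16 of the median-centred calls were among the 26, as were 13 of the 15 with deposited values, 12 of the 13 with floored values and 20 of the 37 without mutant a. The cause was not tested, except that fewer arrays, or fewer probes, enter the fit where these are left out. With fry 5 lists passed, 3 of them among the 10 and 2 that camera did not call. The 10 lists became 0 with an estimated correlation, 6 with the erythroid covariate and 4 to 8 without each array in turn (4 without mutant b, 6 without wildtype d). The Fkbp8 log2 fold change ranged from -6.58 to -4.37 over 18 settings and from -4.54 to -4.37 without each array, always past the threshold. It could not be tested when every array had to be above background. For the other named genes that were called, 223 values kept and 125 lost the call. For those not called, 218 stayed so and 8 gained a call, and 0 values changed direction. In these and all other counts of settings, the deposited table and the scanner's normalized intensity count separately, although their values are the same. A slide block was not run because each slide held 1 array. Probes near background are limited by signal, and a bound stands for the fold where a probe was above background on 0 arrays of a group.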

Other observations

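Lists for axial position, and the signalling and mesoderm lists named here, did not pass camera. Among posterior Hox genes (camera adjusted p = 0.256), Hoxa9 (-0.51, SE 0.09) was the 1 member that fell when adjusted over the list alone, with Hoxb8 at -0.32 (SE 0.09), and anterior Hox genes did not pass (0.28). Retinoic acid response genes had 10 of 15 members negative (camera adjusted p = 0.0785, fry adjusted p = 0.0314), led by Cdx1 (-0.48, SE 0.12) and Rarb (-0.29, SE 0.11). The WNT (0.649), BMP (0.904), FGF (0.928) and NOTCH (0.948) response lists and the list of planar cell polarity and neural tube closure (0.904) did not pass camera at the adjusted p given. Among somite, sclerotome and dermomyotome genes (0.508), the sclerotome gene Pax1 (0.37, SE 0.08) was the 1 member that rose when adjusted over the list alone. The notochord list did not pass (0.904), and Foxa2 was its 1 member that rose over all genes tested. Limb bud (0.369), lateral plate and visceral mesoderm (0.904), intermediate mesoderm (0.729) and gut endoderm with liver and yolk sac (0.948) did not pass.

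Among 24 mitosis genes (camera adjusted p = 0.28), 0 passed over all genes tested in limma (6 at an unadjusted p under 0.05), and 2 fell when adjusted over the list alone, the kinase Aurkb (-0.40, SE 0.08) and the phosphatase Cdc25c (-0.46, SE 0.10). The list of S phase genes did not pass (0.613), and Mcm6 (-0.36, SE 0.08) was its 1 member that fell when adjusted over the list alone. Immediate early genes (0.369) and folate metabolism (0.904) did not pass, and Mthfd1l (0.35, SE 0.08) of the folate list rose when adjusted over the list alone. Over 456 tested X-linked genes the median log2 fold change was 0.01, as it was over 12816 autosomal genes, and 17.5% against 13.3% had an unadjusted p under 0.05.

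Of the tests below, those of neural tissue amount and of sex, and the comparison with other windows of genes, were chosen after the results were seen. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 26 probes and the highest other split 9, and for lists the real split gave 10 and the highest other 5, so in both cases 1 of 10 splits gave as many.

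The ventral list was higher and the intermediate list lower in mutants by camera with its preset correlation (adjusted p = 0.175 and adjusted p = 0.144 with an estimated correlation), with 2 of 6 and 3 of 9 members past the threshold over all genes tested. A different amount of neural tissue in the dissected pieces would move both lists the same way, if their members were made only there. The ventral mean minus the intermediate mean was instead 1.14 log2 units greater in the lowest mutant array than in the highest wildtype array. As far as the members are made only in neural tissue, this argues against a difference in amount alone. Foxa2 and Shh of the ventral list are also made in the notochord. The contrast restates the opposite shifts of the lists that prompted it, and other differences in dissection were not tested. Foxa2 is spotted next to Fkbp8, whose loss could have changed the local background there, but that background was only 0.33 units higher in wildtype, against a spot mean 280.88 units higher in mutants. A difference in sex cannot be told apart from genotype, since 0 wildtype arrays had transcripts of the Y-linked Eif2s3y, Ddx3y and Uty above background and 0 mutant arrays lacked them. An effect of the Fkbp8 mutation on dorsoventral patterning is an untested hypothesis here, since no value in these arrays separates it from sex or slide order.

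Ccdc124 was lower in mutants and lies near Fkbp8. A linked region around the mutation, such as a segment from another strain, may be the source, and it predicts that many neighbours differ. Of the 39 other tested genes among the 20 nearest on each side, 13 (33.3%) had an unadjusted p under 0.05, although 0 passed adjustment in limma. The share was 12.2% over all probes (one-sided exact binomial p = 0.000502) and 13.3% over tested autosomal genes. The binomial test treats genes measured on the same arrays as independent. These 13 neighbours went both ways, as with Rex1bd (0.32, SE 0.08), Rab3a (0.34, SE 0.09) and Upf1 (-0.33, SE 0.08), named after their values were seen. Of 12472 overlapping windows, each without its central gene and its smallest p, 38 (0.3%) held as many or more, and whether sequence variants under probes or altered expression lie behind it stays open. Linkage to Fkbp8 of called genes outside the 20 on each side, such as Bst2, was not examined.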
